A study of Mus musculus with 4 samples.

How the data were processed

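The series holds 4 Affymetrix Mouse Genome 430 2.0 arrays of total RNA from F9 cells, a mouse embryonal carcinoma line that resembles undifferentiated embryonic cells and can be driven to endoderm in culture. Per the labels' protocols, cells were infected with lentivirus carrying the pLKO.1 vector, either with a short hairpin RNA (shRNA) against Phf19 or as the vector control, and stable cells were selected with puromycin. RNA was isolated with a Qiagen RNeasy kit and labelled with biotin under the standard Affymetrix protocol. The labels name 2 biological replicates per group, and the series' design text speaks of 2 cell lines per group. Nothing used here states how many hairpin sequences were used, or whether the replicates came from separate infections, so the p-values measure the spread between these arrays.

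The deposited table gives 1 value per probe set and array, taken here as log2 expression. The scale is not given in the sources used here and was read from the deposited values: they ran from 2.31 to 14.7, and a 16-bit scanner cannot give natural logs above 11.1. The array medians were between 5.75 and 5.76 and the quartiles nearly coincided, so the authors had normalized the arrays to each other before deposit. The software, the summary of probes and the background correction are not given in the sources used here. Summaries of probe sets can compress large fold changes and changes of dim probe sets. The table has no detection calls, so a low value may be background. No scanner files were used.

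Of 45101 probe sets, 64 Affymetrix control probe sets were left out of the tests. Fitted separately with limma, 0 of the 64 had an adjusted p under 0.05 and 1 an unadjusted p under 0.05. The other 45037 were tested without a filter on level. GEO's platform annotation paired 34945 of them with 1 gene symbol and 932 with several, and 9160 were not listed with a gene. Of the 34945, 34741 carried a gene number found in a RefSeq table of assembly GRCm38.p6, which changed 0 of the symbols. The table of values names no genome build, so no coordinates are given. Each of 18193 genes was represented by its single-gene probe set with the highest mean over the 4 arrays, and 9010 genes had more than 1 probe set. A probe set whose name ends in _s_at or _x_at can also hybridise to related transcripts.

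Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), as shPhf19 minus shVector on the log2 scale, two-sided, with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05. The fit has 2 residual degrees of freedom, raised to a median of 6.51 by the moderated variance. Errors given as SE are limma's moderated standard errors, and a group's SD is over its 2 arrays. For 19 probe sets the residual variance was 0, which limma offsets, and none of these passed the threshold. The number of arrays limits the precision of every value.

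Before the data were examined, 20 gene lists with 638 members were fixed (47 members were not analysed here because no probe set was listed with that gene alone). The lists covered Polycomb complexes and their targets, pluripotency, the lineages F9 cells can enter, other cell types, and growth and stress programmes. Each list was tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 20 lists. It was tested again with the correlation estimated from the data. Camera then has only the 2 residual degrees of freedom, so hardly any list can pass and a call lost there decides little. Camera compares a list's genes with all other genes. The rule for named genes was also fixed before: Phf19, the 12 genes with the largest rise and the 12 with the largest fall among genes that passed the threshold, had both shPhf19 arrays on the same side of both shVector arrays and reached the array median in the higher group, and per list up to 4 passing members per direction, or, where none passed, the 2 members with the smallest p. Genes named outside this rule are said to be so.

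The test was checked on simulated values of the 45037 probe sets for the comparison of shPhf19 with shVector, with 4 sets of 50 changed. It recovered 1 of 50 probe sets changed by 0.5 on the log2 scale, 44 of 50 changed by 1, 49 of 50 changed by 1.5 and 50 of 50 changed by 2, and called 9 of 44837 unchanged ones. In the same simulation over 18193 genes, camera called the 1 list shifted by 0.3 and 0 of the 19 unshifted lists. The simulated errors were normal, with variances drawn from the distribution that limma fitted over all probe sets. The check therefore assumed limma's own model. The errors were also independent between genes, so the effect of a correlation between genes on list calls was not checked.

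The groups share replicate numbers, and no label says that a number marks a shared day or batch. Across probe sets the deviations of same-numbered arrays from their group means correlated at -0.197, so the main fit has no replicate term. The alternatives tried were the replicate number as a block, quantile normalization, median centring, leaving out the lowest 25% or 50% of probe sets, the variance without a trend or with robust estimation, a looser and a stricter threshold, the mean of a gene's probe sets, an estimated inter-gene correlation, and leaving out each array. The planned change of pseudocount did not apply to values already on a log scale.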

Results

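Gene expression was measured in F9 embryonal carcinoma cells that stably carried an shRNA against Phf19 (shPhf19, 2 arrays) or the empty hairpin vector (shVector, 2 arrays). Phf19 encodes a Polycomb-like protein that associates with Polycomb repressive complex 2 (PRC2), the complex that methylates histone H3 at lysine 27. The comparison asked which transcripts change when Phf19 is knocked down. The arrays correlated at 0.9974 (Pearson's r over probe sets) within shVector, at 0.9984 within shPhf19, and at 0.9961 to 0.997 between groups. The difference between replicate arrays had an SD over probe sets of 0.192 in shVector and 0.149 in shPhf19 on the log2 scale. The ratio of 3' to 5' signal for beta-actin, a sign of RNA integrity, was 0.995 in shVector and 0.974 in shPhf19 (means of log2 differences), a gap smaller than the 0.322 between the shVector arrays and the 0.104 between the shPhf19 arrays. shVector replicate 1 had the highest ratio (1.16) and the strongest signal of the polyadenylated spike-in controls (8.27 on the log2 scale, against 7.81 to 8.09 in the other arrays).

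Phf19 itself was lower in shPhf19 cells by 1 of its 2 probe sets. Probe set 1427920_at averaged 6.11 ± 0.05 (SD, n = 2) in shVector and 5.13 ± 0.07 in shPhf19 on the log2 scale. This was a change of -0.98 ± 0.10 (SE; limma adjusted p = 0.0108), leaving 50.7% of the control signal with a 95% interval of 43.2% to 59.4%. Probe set 1431857_at did not pass the test, at 6.21 ± 0.15 in shVector and 6.16 ± 0.15 in shPhf19 (change -0.06 ± 0.12, adjusted p = 0.928). The interval of that change runs from -0.35 to 0.23, which excludes the fall seen with the first probe set. The second probe set had the higher mean and therefore stands for Phf19 in counts of genes. Without 1 array, 1427920_at of Phf19 ran from -1.03 to -0.93 and lost the call each time. The adjusted p was 0.114 without shVector replicate 1, 0.147 without shVector replicate 2, 0.692 without shPhf19 replicate 1 and 0.554 without shPhf19 replicate 2. Which part of the transcript each probe set covers was not analysed here.

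**Figure D1:**
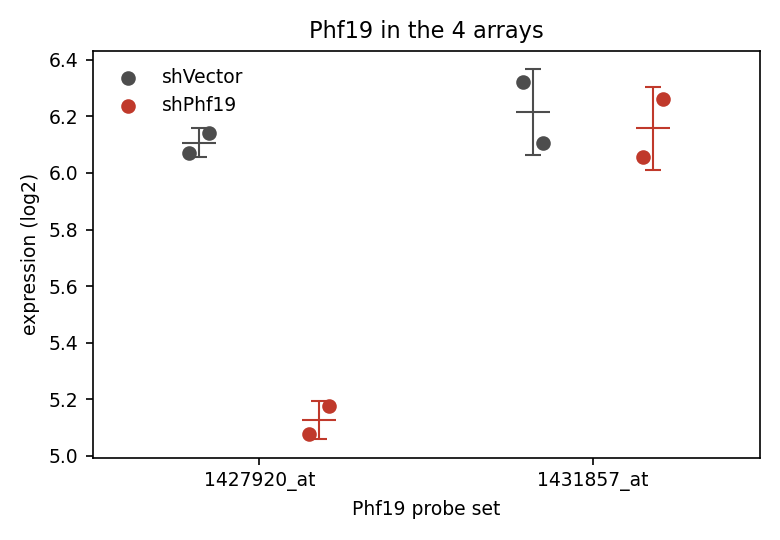
Log2 expression of both Phf19 probe sets in the 4 arrays; points are arrays, horizontal marks the group means and error bars the SD (n = 2). For 1427920_at the shPhf19 arrays lie at 5.08 and 5.17 and the shVector arrays at 6.07 and 6.14, while for 1431857_at the groups overlap.

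Across the transcriptome, 374 probe sets were higher and 262 lower in shPhf19 cells, corresponding to 210 genes that rose and 157 that fell by their representative probe sets. The strongest rise was that of Meioc, a gene of germ cell meiosis, at 5.35-fold (log2 change 2.42 ± 0.10 SE). It was followed by Cubn, the endocytic receptor cubilin of visceral endoderm and kidney, at 4.91-fold (2.30 ± 0.09). The metal ion transporter gene Slc39a8 rose 3.68-fold, although its other probe set was at -0.13 ± 0.09. The transcription factor genes Insm1, Neurod1 and Otx2 rose 3.52-fold, 2.70-fold and 2.65-fold. Lef1, a transcription factor of the Wnt pathway, rose 2.86-fold. Efnb2, which encodes the membrane ligand ephrin-B2, rose 2.81-fold, with 1 of its other 3 probe sets also passing. Dab2, an endocytic adaptor abundant in extraembryonic endoderm, rose 2.64-fold. Stox2 (2.69-fold), Zfp365 (2.68-fold) and Fam171b (2.63-fold) completed the 12.

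The largest fall was that of Rpl39l, a paralog of the ribosomal protein gene Rpl39, at 4.91-fold (log2 change -2.30 ± 0.10 SE). Krt17, an epithelial keratin gene, fell 4.01-fold (95% interval of the log2 change -2.22 to -1.78). Serpinf1, which encodes a secreted serpin, fell 3.39-fold, and Hhip, an antagonist and target of Hedgehog signalling, fell 3.19-fold with all of its other 3 probe sets passing in the same direction. Sgms2, a sphingomyelin synthase gene, fell 3.08-fold. Msln, which encodes mesothelin, fell 2.90-fold. Serpinb6c fell 2.87-fold, Smim22 2.85-fold, Inhbe 2.68-fold, Fetub 2.66-fold, B230217C12Rik 2.61-fold and Fam174a 2.49-fold. The other probe set of Smim22 did not fall (0.10 ± 0.10). The names of the Serpinb6c, Smim22, Cubn and Stox2 probe sets carry suffixes of probe sets that can hybridise to related transcripts, and hybridisation of the Rpl39l probe set to Rpl39 was not analysed here.

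**Figure D2:**
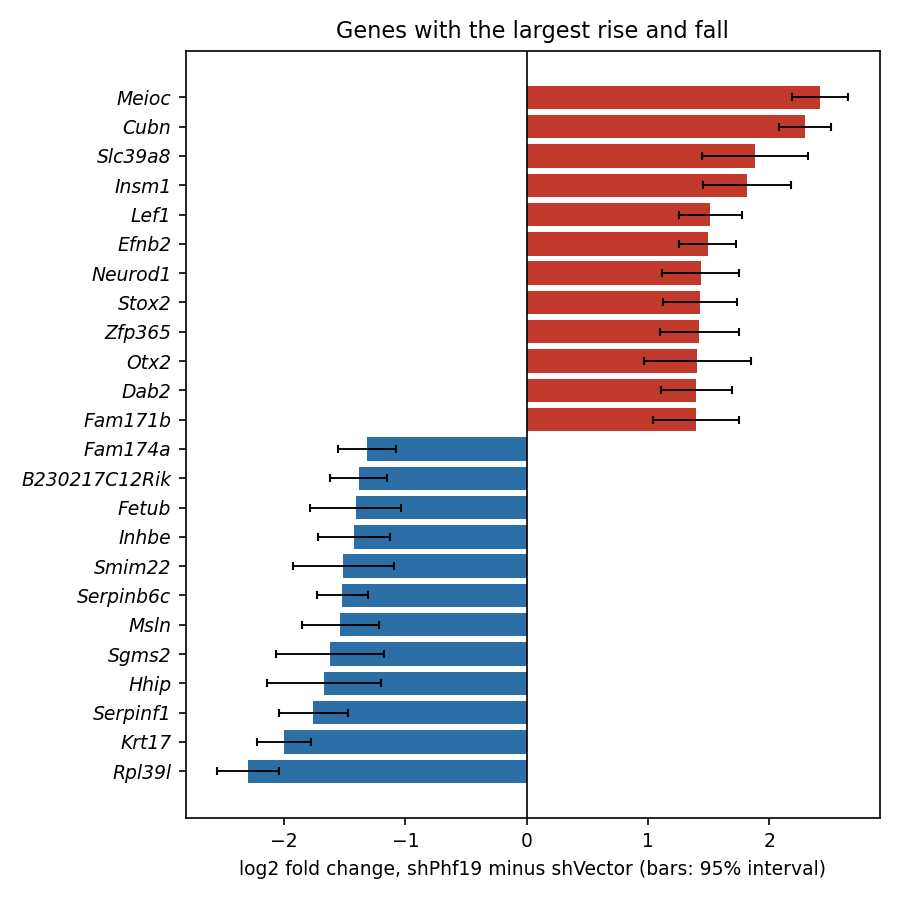
Log2 fold change (shPhf19 minus shVector, x axis) of the 12 genes with the largest rise and the 12 with the largest fall; bars start at 0 and error bars are 95% intervals from limma. Changes run from -2.30 for Rpl39l to 2.42 for Meioc, and no interval reaches 0.

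Adjusted p-values (limma, Benjamini-Hochberg) of these 24 genes lay between 0.00147 for Cubn and 0.0244 for Otx2. All 636 called probe sets had both shPhf19 arrays on the same side of both shVector arrays, which a call nearly requires. Among all probe sets this held for 40.5%, against 33.3% expected by chance for 2 arrays against 2. That excess was not tested, since all probe sets share the same 4 arrays. Of the called probe sets, 79 rose and 44 fell by 2-fold or more, and no gene had called probe sets in both directions. With any 1 of the 4 arrays left out (shVector replicate 1 or 2, or shPhf19 replicate 1 or 2), limma called 0 probe sets at the same threshold, with 2539 to 6942 at an unadjusted p under 0.05 against 5708 in the complete data. Each fit without an array leaves 1 array in that group, so its residual spread comes from the other group alone. Without an intensity trend in the variance, 220 of the 367 genes were called again.

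Genes of primitive and parietal endoderm, among the lineages that F9 cells can form when they differentiate, changed in both directions. The list also held genes of visceral endoderm, such as Cubn. Of 36 measured members, 7 rose, 2 fell and 27 did not pass. Besides Cubn and Dab2, the basement membrane genes Col4a1 (2.06-fold, log2 change 1.04 ± 0.08 SE), Col4a2 (2.04-fold) and Lamb1 (1.88-fold) rose. So did Gata6, a transcription factor that specifies primitive endoderm (2.28-fold), and its lineage's receptor gene Pdgfra (2.26-fold). Gata6 and Pdgfra were named after their values were seen. The other probe sets of Gata6 (0.08 ± 0.10 and 0.00 ± 0.09) and Pdgfra (0.13 ± 0.10 and 0.46 ± 0.09) did not pass. Nor did those of Dab2, which ran from 0.09 to 0.44. All of these were dimmer than the representative probe sets. Krt8, a keratin of simple epithelium, fell 2.10-fold with both of its other probe sets passing, and Nid1, which encodes the basement membrane protein nidogen, fell 1.42-fold. Other endoderm genes, also picked afterwards, did not pass: Gata4 was at 0.38 ± 0.10, Sox7 at -0.24 ± 0.11, Foxa2 at 0.30 ± 0.13 and Sparc at -0.12 ± 0.06. For Sox17 the representative probe set was at 0.27 ± 0.11, whereas its second, 1429177_x_at, rose 2.66-fold. Camera called the list higher (adjusted p = 0.0156), although its median change was only 0.01 against a mean of 0.23. The call was lost with an estimated correlation (adjusted p = 0.271), without shVector replicate 1 (adjusted p = 0.0776) and with a block of crossed replicate numbers, chosen after seeing the data (adjusted p = 0.071), and the adjusted p ranged from 0.00372 to 0.271 over the alternatives. Adjusted over the list alone, 12 members rose and 3 fell.

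Germline genes rose in part. Of 23 measured members, 3 rose and none fell: Ddx4, the germ cell RNA helicase Vasa (2.14-fold), Dmrt1, a transcription factor of the testis and germ line (1.91-fold), and Tex15, a gene of spermatogenesis (1.57-fold). The list's median change was 0.16, and camera called it higher (adjusted p = 0.00873). That call did not hold with an estimated correlation (adjusted p = 0.271), without shVector replicate 1 (adjusted p = 0.0599) or with the lowest 50% of probe sets left out (adjusted p = 0.308), with a range from 0.00118 over the alternatives. Adjusted over the list alone, 9 rose and 2 fell. Imprinted genes, which are expressed from 1 parental allele, showed 4 rises and no fall among 29 measured. Cdkn1c, a cyclin-dependent kinase inhibitor gene, rose 2.22-fold (log2 change 1.15 ± 0.12 SE), Phlda2 1.88-fold, Peg10 1.83-fold and Mirg 1.39-fold. Rian and Meg3, noncoding RNA genes of the same imprinted cluster as Mirg that were named afterwards, did not pass by their representative probe sets (0.31 ± 0.05, adjusted p = 0.0501, and 0.42 ± 0.09). Further Meg3 probe sets passed, at 0.44 ± 0.06 and 0.58 ± 0.08. The list's median was 0.20, with 21 of 29 members above 0 (camera adjusted p = 4.54e-06, and adjusted p = 0.271 with an estimated correlation). Adjusted over the list alone, 11 rose and none fell.

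Targets of p53 and CDK inhibitor genes had the highest median change of the 20 lists, at 0.27. Of 27 measured members, 6 rose, 1 fell and 20 did not pass. Plk2 rose 2.04-fold, Ccng1 1.76-fold (log2 change 0.82 ± 0.06 SE) and Trp53inp1 1.61-fold, all known p53 targets, although the second Plk2 probe set was at -0.29 ± 0.11. Eda2r (1.44-fold) and Ddit4l (1.63-fold), named afterwards, and Cdkn1c were the other rises. Cdkn2a, the locus of p16 and p19Arf, fell 1.91-fold. The p53 target Cdkn1a was at -0.05 ± 0.15 and Mdm2 at 0.34 ± 0.09, and neither passed. Camera called the list higher (adjusted p = 3.65e-07), but not with an estimated correlation (adjusted p = 0.271). Adjusted over the list alone, 14 rose and 2 fell.

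Genes of the unfolded protein and integrated stress response moved the other way. Of 40 measured members, 7 fell, none rose, and 34 of the 40 had a change below 0 (median -0.17). The cystine transporter gene Slc7a11 fell 1.86-fold (log2 change -0.89 ± 0.10 SE), the transcription factor gene Cebpb 1.59-fold, Atf5 1.49-fold and Stc2 1.49-fold. Atf4, which encodes the central transcription factor of the integrated stress response, fell 1.23-fold (-0.30 ± 0.05), Mthfd2 of mitochondrial folate metabolism 1.29-fold, and Vldlr 1.40-fold; these were named afterwards. Camera gave the list its smallest p of all lists (adjusted p = 1.78e-11), again lost with an estimated correlation (adjusted p = 0.271). Adjusted over the list alone, 17 fell and none rose. Cholesterol synthesis genes shifted little: none of 20 passed (1 fell, adjusted over the list alone), with Ebp at -0.33 ± 0.06 and Lss at -0.21 ± 0.06. The other Lss probe sets were at 0.03 ± 0.09 and -0.04 ± 0.07. The list's median was -0.13 with 18 of 20 below 0, and camera called the list lower (adjusted p = 0.00306, and adjusted p = 0.271 with an estimated correlation).

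**Figure D3:**
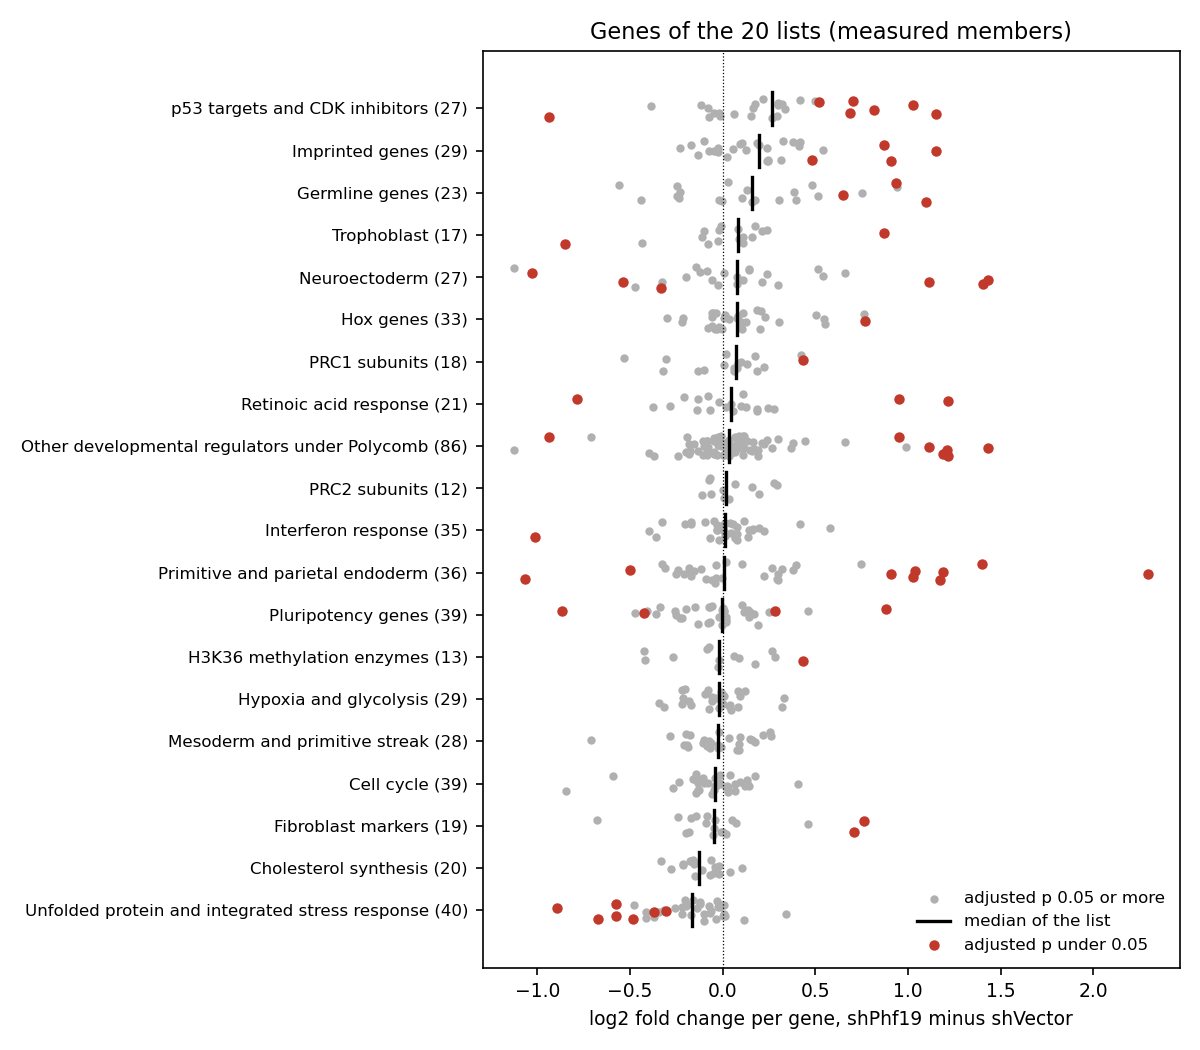
Log2 fold change (shPhf19 minus shVector, x axis) of each measured member of the 20 lists (rows, number of members in parentheses); red points passed adjusted p under 0.05 and black marks are list medians. Medians run from -0.17 for the unfolded protein and integrated stress response to 0.27 for p53 targets and CDK inhibitors.

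Few genes of Polycomb components passed the test. Among 12 other PRC2 subunit genes none passed; Jarid2 was at 0.30 ± 0.05 (adjusted p = 0.0593) and Aebp2 at 0.28 ± 0.08, while the core genes Ezh2 (-0.11 ± 0.05), Suz12 (0.16 ± 0.06) and Eed (0.00 ± 0.10), named afterwards, lay closer to 0. Another Jarid2 probe set passed, at 0.28 ± 0.04 (adjusted p = 0.0467). Camera gave adjusted p = 0.256, and 1 member, Jarid2, rose when adjusted over the list alone. Of 18 PRC1 subunit genes, 1 rose, Kdm2b (1.35-fold), which encodes a CpG island-binding H3K36 demethylase (camera adjusted p = 0.426; adjusted over the list alone, 3 rose and 3 fell). Kdm2b was also the only passing member of the 13 H3K36 methylation enzyme genes (camera adjusted p = 0.843; adjusted over the list alone, 3 rose and 2 fell). For that list camera's direction was up, while its median was -0.02; without replicate 1 of either group the direction was down.

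Polycomb target classes changed in a minority of members. Of 33 Hox genes, 1 rose, Hoxd9 (1.71-fold, log2 change 0.77 ± 0.12 SE); its neighbours Hoxd8 (0.50 ± 0.10) and Hoxd10 (0.76 ± 0.14), named afterwards, were above 0 without passing. The Hox list stood at camera adjusted p = 0.0514, just short of the threshold. It passed with quantile normalization (camera adjusted p = 0.0426), without a variance trend (0.0373) and with the mean of probe sets (0.0175). It moved away from the threshold without the lowest 25% of probe sets (camera adjusted p = 0.154) and without the lowest 50% (0.492). With an estimated correlation it stood at adjusted p = 0.578. The shift therefore rested in part on dim probe sets. In this list 4 rose when adjusted over the list alone. Of 86 other developmental regulators under Polycomb control, 6 rose and 1 fell. En2, a homeobox gene of the midbrain and hindbrain, rose 2.31-fold, Sox1, a gene of the neural plate, 2.16-fold, Neurod1 2.70-fold and Meis2 1.93-fold; Gata6 and Meis1 were the other rises, and the member that fell was Cdkn2a. The second Sox1 probe set was at -0.15 ± 0.10. The other Meis1 probe sets were at 0.70 ± 0.13 and -0.14 ± 0.10 and did not pass. Camera did not call this list (adjusted p = 0.133), and adjusted over the list alone 8 rose and 4 fell. Neuroectoderm genes split evenly, with 3 rising (Sox1, Neurod1, Otx2) and 3 falling among 27: Zic2, a zinc finger gene of neural development, fell 2.04-fold, Tubb3 1.45-fold and Stmn2 1.26-fold (camera adjusted p = 0.607; adjusted over the list alone, 6 rose and 6 fell). In the retinoic acid response list of 21, Meis1 (2.32-fold) and Meis2 rose and Aldh1a2, which encodes a retinoic acid synthesising enzyme, fell 1.72-fold (camera adjusted p = 0.537; adjusted over the list alone, 2 rose and 1 fell).

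Pluripotency genes moved in both directions, and 35 of 39 measured did not pass. Dnmt3l, a cofactor of de novo DNA methylation, rose 1.84-fold and the methyltransferase gene Dnmt3b 1.22-fold, while Lefty2, an antagonist of Nodal signalling, fell 1.82-fold and Jam2 1.34-fold. The core factors Pou5f1 (0.02 ± 0.04), Sox2 (0.02 ± 0.04) and Nanog (-0.26 ± 0.05, adjusted p = 0.0923), named afterwards, did not pass over all probe sets, although the 95% interval of Nanog, from -0.38 to -0.13, lay below 0. Camera gave adjusted p = 0.256, and adjusted over the list alone 6 rose and 10 fell. No member passed among 28 mesoderm and primitive streak genes (Tbx20 -0.71 ± 0.12, Mesp2 0.26 ± 0.09; camera adjusted p = 0.631), 39 cell cycle genes (Ccnd3 -0.59 ± 0.11, Ccne2 -0.84 ± 0.18; camera adjusted p = 0.253) or 29 hypoxia and glycolysis genes (Egln1 -0.32 ± 0.07, Hk2 -0.22 ± 0.06; camera adjusted p = 0.376). Adjusted over each list alone, 1 mesoderm gene, 3 cell cycle genes and 0 hypoxia and glycolysis genes fell and none rose.

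Markers of other cell types were checked in the same fit. Of 17 trophoblast genes, Peg10 rose and Tfap2c fell 1.81-fold (camera adjusted p = 0.631; adjusted over the list alone, 1 rose and 2 fell). Of 19 fibroblast markers, Mmp2 (1.63-fold) and Loxl1 (1.70-fold), which encode extracellular matrix enzymes, rose (camera adjusted p = 0.843; adjusted over the list alone, 3 rose and 1 fell). The mean change of that list was 0.01, its median -0.05 and camera's direction down, which turned to up with either filter on dim probe sets or without shPhf19 replicate 1. Among 35 interferon response genes, which viral vectors can induce, 1 changed: Xaf1 fell 2.02-fold (camera adjusted p = 0.9998; adjusted over the list alone, 2 rose and 2 fell). For that list the mean was -0.01, the median 0.01 and camera's direction up. Without a call, that direction turned to down with median centring, either filter on dim probe sets, the crossed block, or either replicate 2 array left out.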

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

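The block with crossed replicate numbers was chosen after seeing the data; the other alternatives here were planned. The call of Phf19 and all counts of called genes depended on the arrays and the model. The directions of called genes did not change, but this was largely given. All called probe sets separated the groups fully, so leaving out an array could not reverse a sign. The blocks and variance settings leave the change itself as it is. Without 1 array in turn, limma called from 0 to 0 probe sets and genes in either direction (6942 and 5464 probe sets at an unadjusted p under 0.05 without shVector replicate 1 and 2, and 2539 and 2785 without shPhf19 replicate 1 and 2), and Phf19 probe set 1427920_at ran from -1.03 to -0.93 without passing, while 1431857_at ran from -0.16 to 0.05. Median total degrees of freedom were 3.83 to 4.01 there, against 6.51. Simulated data with 1 array fewer still gave calls. Those values had independent errors and variances drawn from limma's fitted distribution, which the data need not follow. They therefore do not settle whether fewer arrays alone account for the loss. The cause was not tested. The replicate number as a block also gave 0 probe sets and 0 genes higher and lower (3890 probe sets at an unadjusted p under 0.05) and left Phf19 at -0.98 (adjusted p = 0.203, against 0.00511 to 0.692 over its alternatives); the numbers share no stated day, and over all probe sets the deviations of same-numbered arrays correlated at -0.197. That crossed block called 337 probe sets higher, 259 lower and 5 gene lists, without the endoderm list. Without a variance trend, 229 probe sets and 129 genes were higher and 151 and 91 lower. At an adjusted p under 0.10 these were 657, 365, 493 and 304, and with a 2-fold minimum 79, 45, 44 and 29. With the mean of a gene's probe sets, 261 genes were lower. Under quantile normalization, median centring, robust variance and both filters on dim probe sets, counts stayed within 1.5 times, and all of the 367 genes still tested were called again (344 of 344 without the lowest 50% of probe sets, 365 of 365 without the lowest 25%); the 50% filter left out Phf19 probe set 1427920_at, which has no value there. The 6 list calls became 0 with an estimated correlation (smallest adjusted p = 0.271) and 4 to 7 without 1 array; the replicate block changed 1 list call, bringing the Hox genes to adjusted p = 0.0271 (0.0175 to 0.578 over the alternatives). An estimated correlation leaves camera 2 degrees of freedom, so the calls lost there decide little about the lists. With the mean of probe sets the other developmental regulators reached a camera adjusted p = 0.0142. No called gene or list reversed under any alternative run, which for the genes was largely given, as said above. Dim probe sets limit what can be seen, since the table has no detection calls and a level near the lower quartile may be background. The planned change of pseudocount was not run, since the values are already on a log scale.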

Other observations

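All tests in this part except those on neighbouring genes and on the difference in expression level were chosen after the results they bear on had been seen. Several smaller gene groups, chosen from the values, add to the description. Of the 4 Id genes, inhibitors of basic helix-loop-helix factors and targets of BMP signalling, Id4 fell 2.29-fold and Id2 rose 1.85-fold, while Id3 (-0.78 ± 0.18 SE) and Id1 (-0.01 ± 0.12) did not pass (limma, adjusted over all probe sets). Of 8 Hedgehog pathway genes, Hhip and Gli1 (1.70-fold) fell and none rose; Ptch1 was at -0.26 ± 0.05 without passing. Of 19 Sox genes, Sox1, Sox11 (1.95-fold) and Sox4 (1.91-fold) rose and none fell. Ebf1, a transcription factor of neural and lymphoid development, rose 2.51-fold with 3 of its other 4 probe sets passing. The carbonic anhydrase genes Car3 (2.57-fold) and Car14 (2.48-fold) rose among 16 measured. Among 13 Wnt pathway targets Lef1 rose and Notum fell 1.43-fold, with Axin2 at 0.38 ± 0.11 without passing. Of 18 immediate early genes, Fos fell 2.19-fold and Jun rose 1.52-fold, and Egr1 was at -0.62 ± 0.21 without passing. Keratins fell in 2 of 48 measured genes (Krt17 and Krt8), 1 of 12 S100 genes fell (S100a6, 2.32-fold), and 1 of 20 glutathione S-transferase genes fell (Gstm2, 2.27-fold).

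The 210 genes that rose and 157 that fell were weighed against chance and copy number. The 4 arrays allow 3 splits into pairs, too few for a share under 0.05: the real split, 1 of the 3, called 636 probe sets and the highest of the others 0 (856 and 2197 probe sets at an unadjusted p under 0.05). A gain or loss of a chromosome segment in one of the stable lines would move neighbouring genes together. Over 11150 ordered genes at or above the median level, 9 windows of 25 neighbouring genes went beyond the 95th percentile of the largest window in 1000 permuted gene orders (0.231 on the log2 scale), and they held 2.62% of the 343 called genes, which argues against segments as the main source. The highest window (mean 0.256) held Nexmif, Lpar4, Itm2a and Sh3bgrl, X-linked genes that rose 2.16-, 1.91- and 1.65-fold and, for Sh3bgrl, by 0.58 on the log2 scale. The other 21 of its 25 genes did not pass, and changes of genes lying between these 4 ran from -0.08 (Atp7a) to 0.48 (Hmgn5). An effect of the hairpin on other transcripts, or drift between the stable lines, was not tested and stays open beside the knockdown itself.

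For the endoderm genes, a share of fibroblast-type cells would bring their abundant products. The median change of Col1a1, Col1a2, Col3a1, Fn1 and Vim was -0.00789 (highest 0.07). Their mean was -0.05 ± 0.05, where the error is the standard error over these 5 genes and not over arrays. This was below 0.52, the level set as the minimum from the Col4a1 rise. Mmp2 and Loxl1, which were not among these 5, rose by 0.71 and 0.76, while 17 of the 19 measured fibroblast markers did not pass. Neither the 5 products, picked after the values were seen, nor the 19 markers fixed before rose as a set (median of the 19 -0.05). This argues only against a share large enough to raise these markers together. Products bright in the control could hide a small share. A share of cells that had turned into parietal endoderm would raise all of that lineage's abundant products. Of 12 such genes 3 rose (Lamb1, Col4a1, Col4a2) and 2 fell (Krt8 and Nid1), and the median change of the 12 was -0.0870 (SD 0.64 over genes), below the 1.04 of Col4a1 by more than that SD. Col4a1 had the largest rise of the 12, so their median had to lie below it, and that gap decides nothing. The 12 did not rise as a set, but products bright in the control could hide a share of such cells. Endoderm genes with larger rises, such as Cubn and Gata6, were not among the 12. A share of parietal endoderm cells therefore stays open. Partly differentiated cells and a change within all cells were not tested and stay open.

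The shifts of the p53 list (6 of 27 members rose) and the stress response list (7 of 40 fell) may reflect RNA quality or labelling. Camera called both lists with the preset correlation between genes. It called neither with an estimated correlation, which leaves it 2 degrees of freedom and decides little. The group difference in the actin 3' to 5' ratio, multiplied by each gene's slope on that ratio between the shVector arrays, gave at most 2.13% of the lists' medians (0.27 for the p53 list and -0.17 for the stress response list). This decides nothing, because the group gap was only 6.63% of the gap between the shVector arrays, so that such a slope could hardly give more, and because the ratio does not measure labelling. RNA quality and labelling therefore cannot be told apart from the other explanations for these lists. Differences in cell density, medium or selection between the cultures were not tested and stay open, as does the knockdown.

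A hypothesis set out before its test was that genes kept at low levels are released when Phf19 is reduced. The median level of the genes that rose minus that of the genes that fell was -0.97 on the log2 scale. This decides nothing, because levels of different probe sets have no common scale, and the hypothesis stays untested.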
